A study of Arabidopsis thaliana with 27 samples.

How the data were processed

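Small RNA of etiolated Arabidopsis hypocotyls was measured in 27 libraries, 3 for each of 9 groups made of 3 genotypes (wild type Columbia-0, xpf-3, uvr8-6) and 3 treatments (dark, 3000 or 30000 µmol per square metre UV-B). Per the labels, seeds were kept in the dark for 2.5 days on 0.5x MS with 100 µM GA4 before exposure, hypocotyls were excised 6 hours after it (the series title gives 2 days), and libraries were made with the Clontech SMARter small RNA kit. Groups were formed from the genotype and treatment labels and the sample titles.

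The deposited raw sheets hold whole-number read counts per annotated locus, with a sheet for all small RNAs and another for miRNAs, and these counts were the values tested. The deposited normalized sheets hold a signal per locus and library, which equalled the deposited count divided by a median-of-ratios size factor for each library (100% of values within 0.01) and left out loci with a total of 1 count or less (1686 and 288 loci kept). They were used for this check alone. Reads were quality checked with FastQC and trimmed with cutadapt, per the submitters' processing notes, which give no versions. The aligner, the counting tool, the treatment of reads with several matches and the genome build are not given in the sources used here. The miRNA sheet equalled the miRNA part of the sheet of all small RNAs in every cell. In all, 218 deposited columns were not used. Gene names, mature sequences and neighbouring genes were taken from TAIR10.1, and coordinates were not used.

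Depth per library is the sum of its counts. Group means of the total (SD) were 1148790 (482231) for wild type dark, 1100700 (124104) and 1020060 (320846) after the lower and higher dose, 1270748 (289023), 1352630 (370296) and 1522188 (234056) for xpf-3, and 1013870 (288165), 1266480 (271955) and 1451610 (455046) for uvr8-6. Group means of miRNA counts were lowest at 31766 (19096) in wild type after the higher dose and 32280 (10950) in uvr8-6 after the higher dose. Over all small RNAs the chi-square per degree of freedom of pairs of replicates was 32.2 to 178 (27 pairs), many times the value that counting error alone gives. Loci with many counts, most of them rRNA counts, weigh most in this measure. For loci with few counts counting error can be a larger part of the spread. Fold limits and ratios given for loci with few counts cover counting error only. A locus at 0 counts was given a limit against 3 counts over the group.

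Each table was tested in R 4.3.3 with edgeR 4.0.16: TMM factors, filterByExpr with a minimum count of 10, and a quasi-likelihood fit of all 27 libraries in 9 groups, with 18 residual degrees of freedom. It left 101 miRNAs and 1109 loci of all small RNAs. The 14 comparisons were each dose against dark in each genotype and in the mean of the genotypes, each mutant against the wild type in the dark, and the difference of each mutant's response from that of the wild type. A locus was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison and table. The standard error is the log2 change over the square root of F. Loci were named by a rule fixed before the data were examined: called, a mean of at least 10 CPM, and no overlap between the groups (for means, the same sign in the 3 genotypes). The 15 highest and 15 lowest changes were taken in the higher-dose comparisons of the wild type and of the mean, 5 and 5 elsewhere. Where fewer than 5 passed, the 5 with the smallest p were kept as values that did not pass. The 10 most abundant miRNAs and called members of the lists were added, and not all named loci are printed. The loci in the figures of single miRNAs and those printed over the 3 doses were picked after their values were seen.

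The 12 lists of miRNA families were fixed before the data were examined: phase change, auxin signalling, copper, phosphate and sulfate, miRNA machinery, growth transcription factors, MYB of the phenylpropanoid pathway, triggers of secondary siRNAs, light-regulated, predicted UV-B-induced, NF-Y and drought, and other organs than the hypocotyl. They were drawn up from memory of known targets. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and again with an estimated correlation, and with fry (limma), over lists of at least 3 tested members. The fry test asks whether members changed, in a common direction or in either, and not whether they changed more than other miRNAs. Its values are still scaled to the miRNA counts. That minimum was set after first list tests had been seen; without it 4 tests of a list in a comparison passed in place of 3, adding phosphate and sulfate (higher) in dark xpf-3, at camera adjusted p = 0.0452.

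Shares of the 5 classes were tested by exact permutation, with 20 arrangements of 3 against 3 libraries and 8000 within genotype. All arrangements were listed in place of the random draws first planned. Agreement between genotypes is Pearson's r of log2 changes across miRNAs. The comparison of each mutant with the wild type over the 3 doses, the family interactions, the leaving out of rRNA and the keeping of near-identical loci once were added after the data had been seen.

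Alternatives tried were DESeq2 1.42.0, RLE factors, no low-count filter, the replicate number as a block, only the groups compared, library sizes of the table of all small RNAs for miRNAs, and leaving out each library. The library sizes of all small RNAs were the totals in the fit of that table times their TMM factors (0.730 to 1.34). Calling was tested on simulated data with the depth and spread of these libraries, 5 simulations each. For miRNAs edgeR recovered 39.7% of 2-fold and 71.4% of 4-fold changes in the higher-dose comparison of the wild type, 69.0% and 87.3% in that of the mean, 45.1% and 61.1% between uvr8-6 and wild type in the dark, and 14.3% and 59.7% in the interaction. For all small RNAs the shares were 19.0% and 45.5%, 50.9% and 71.0%, 16.5% and 46.4%, and 5.67% and 32.0%. False calls were at most 4.71% of calls. Loci were drawn independently and changed in random directions, so false calls with correlated loci or a shift of a whole class were not measured. A list shifted 2-fold was called by camera in 5 of 5 simulations, and 0 of 40 other lists, again with members drawn independently. Real groupings were compared with other groupings of the same libraries, all 10 for 3 against 3, and 100 drawn at random for means or 50 for interactions.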

Results

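Small RNAs were sequenced from the hypocotyl, the seedling stem, of Arabidopsis thaliana seedlings grown in the dark. The seedlings were wild type (Columbia-0), xpf-3 or uvr8-6. XPF is an endonuclease subunit of nucleotide excision repair, which removes UV-induced DNA lesions, and UVR8 is the UV-B photoreceptor. Each genotype was kept in the dark or given UV-B at 3000 µmol per square metre (the lower dose) or 30000 µmol per square metre (the higher dose). The 9 groups held 3 replicate libraries each, 27 in all. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical. The labels also give 2 times for collection after UV-B, 2 days in the series title and 6 hours in the extraction protocol. XPF and UVR8 transcripts were not measured by this assay, so the genotype labels could not be checked against the mutated genes.

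The deposited counts covered 2071 annotated loci, of which 323 were miRNA genes, 528 rRNA, 378 snoRNA, 152 snRNA and 690 tRNA loci. The total count of a library ranged from 681228 (uvr8-6 dark replicate II) to 1970871 (uvr8-6 30000 replicate I), with a median of 1173114. miRNA counts ranged from 15790 (wild type, higher dose, replicate III) to 67899 (wild type dark replicate II), with a median of 42180. In dark wild-type hypocotyls rRNA fragments made up 74.8% ± 2.65 (SD, n = 3) of counts, tRNA fragments 13.3% ± 3.85, miRNA loci 4.81% ± 1.74, snRNA 3.78% ± 0.535 and snoRNA 3.31% ± 0.260. The 10 most abundant miRNA loci of each library, which can differ between libraries, held a mean of 68.3% of its miRNA counts. In the mean of all 27 libraries MIR169C led with 12.4%, and MIR169A held 9.67% and MIR169B 5.11%. The order differed between groups. In dark wild type MIR396A was above MIR169C, at 120802 ± 12047 against 105276 ± 32871 CPM (SD, n = 3). In dark uvr8-6 MIR169A was above it, at 121008 ± 28743 against 94306 ± 19407 CPM. The miR169 family targets NF-YA transcription factors. MIR158A held 11.1%, MIR396A, whose product targets growth-regulating factors, 7.14%, and MIR822A 4.57%. MIR156C, MIR156F and MIR156B, sources of miR156, which targets SPL transcription factors, held 5.05%, 4.50% and 2.86%. MIR8175 held 5.12%, and its mature sequence also lies at the 3′ end of 22 tRNA-Asp genes, so this locus is uncertain. The locus counts hold every fragment of a hairpin, and mature and passenger strands were not separated. Abundances of miRNAs are given in CPM, counts scaled to a common total of miRNA counts per library, and their changes are therefore relative to other miRNAs.

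The first comparison asked which miRNAs differed after the higher UV-B dose in the wild type. MIR319B (AT5G41663), a source of miR319, which targets TCP transcription factors, fell by 1.15 ± 0.20 on the log2 scale (SE, n = 3 per group, edgeR adjusted p = 0.000737), from 12081 to 5410 CPM. MIR169J, MIR156F and MIR156E fell by 1.35 ± 0.31, 0.89 ± 0.26 and 0.84 ± 0.26. MIR165A, MIR166B and MIR171B, from families that target HD-ZIP III and GRAS transcription factors, changed by −0.75 ± 0.18, −2.73 ± 0.64 and −1.92 ± 0.55. MIR167D and MIR164C, from families that target auxin response factors and NAC genes, fell by 1.21 ± 0.32 and 0.96 ± 0.26. MIR169N was listed at 0 counts after UV-B against 66 in the dark, at least 13.4-fold lower against a floor of 3 counts over the group. MIR5642a (AT3G06345) rose by 4.59 ± 0.84 (edgeR adjusted p = 0.000955), from 208.5 ± 158 to 5203 ± 2828 CPM (SD). MIR399C, from the phosphate-starvation family miR399, rose by 2.49 ± 0.73, MIR2936 by 1.95 ± 0.56, and MIR160A, whose family targets auxin response factors, rose from 2871 ± 380 to 5772 ± 1580 CPM (SD). MIR8176 rose by 0.86 ± 0.28, but its value was −0.08 with the library sizes of the table of all small RNAs, and its hairpin overlaps the snoRNA AT4G07075. Among the 10 most abundant loci MIR156F alone passed, and MIR396A was at −0.71 ± 0.25 (edgeR adjusted p = 0.0568).

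In total 15 of 101 tested miRNAs passed edgeR's adjusted p of 0.05 in this comparison, 5 higher and 10 lower, and 29 had an unadjusted p under 0.05. All 15 had groups that did not overlap, as did 29.7% of the tested miRNAs, where chance gives 10%. With the library sizes of the table of all small RNAs the median of all miRNAs shifted by −0.92 and 28 were called, 1 higher and 27 lower, and with no low-count filter 14 were called, 1 higher and 13 lower. Without the higher-dose replicate III, the library with the fewest miRNA counts, 7 were called.

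In xpf-3 the higher dose was followed by lower MIR169J (−2.08 ± 0.32, n = 3 per group, edgeR adjusted p = 0.00014), which went from 12895 to 3043 CPM. MIR156F and MIR156E fell by 1.25 ± 0.26 and 1.16 ± 0.26, MIR396A by 1.14 ± 0.25, MIR319B by 0.84 ± 0.19, MIR166B by 1.96 ± 0.61 and MIR164B by 2.18 ± 0.64. MIR167A and MIR167B rose by 2.21 ± 0.61 and 3.24 ± 0.84, MIR5642b and MIR5642a by 3.82 ± 1.07 and 2.83 ± 0.77, and MIR403, whose product targets an ARGONAUTE gene, by 0.86 ± 0.28. MIR390A, which triggers the TAS3 siRNAs that act on auxin response factors, rose by 0.82 ± 0.22 and MIR156C by 0.52 ± 0.17, but with the library sizes of all small RNAs their values were −0.06 and −0.32. The test called 16 miRNAs, 9 higher and 7 lower, with 29 at an unadjusted p under 0.05. With the library sizes of all small RNAs it called 33 (3 higher, 30 lower), with DESeq2 28 (11 higher, 17 lower), with RLE size factors 20 (9 higher, 11 lower) and with no low-count filter 20 (5 higher, 15 lower). Without xpf-3 dark replicate I, dark replicate III or higher-dose replicate III the count was 8, and without dark replicate II or higher-dose replicate I 9.

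In uvr8-6 the higher dose was followed by lower MIR156F (−1.05 ± 0.26, edgeR adjusted p = 0.0386), MIR396A (−0.93 ± 0.25, edgeR adjusted p = 0.0413) and MIR319B (−0.76 ± 0.20, edgeR adjusted p = 0.0386), with 3 libraries per group. MIR396A went from 60228 ± 22410 to 31604 ± 11578 CPM (SD), and in each of these 3 miRNAs the groups did not overlap. MIR390A was at 0.63 ± 0.22 and MIR165A at −0.52 ± 0.18, and neither passed (edgeR adjusted p = 0.15 for each). The 3 calls stood beside 20 miRNAs at an unadjusted p under 0.05. The count was 0 without dark replicate I, higher-dose replicate II or higher-dose replicate III, 5 without dark replicate III, and 1 when only the groups compared were fitted.

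Averaged over the 3 genotypes, the higher dose changed 35 of 101 miRNAs, 19 higher and 16 lower, with 44 at an unadjusted p under 0.05. MIR319B fell by 0.92 ± 0.11 (edgeR adjusted p = 4.98e-06, n = 9 per condition), MIR169J by 1.41 ± 0.18 (4.98e-06), MIR156F by 1.06 ± 0.15 (1.37e-05) and MIR396A (AT2G10606) by 0.93 ± 0.14 (4.06e-05). MIR165A, MIR166A and MIR166B fell by 0.54 ± 0.10, 0.36 ± 0.14 and 1.70 ± 0.35, MIR164B and MIR164C by 1.74 ± 0.38 and 0.60 ± 0.15, and MIR171B by 1.08 ± 0.30. MIR167C and MIR167D fell by 1.10 ± 0.36 and 0.89 ± 0.18, MIR156E by 0.89 ± 0.15, MIR319C by 0.54 ± 0.16 and MIR390B by 0.37 ± 0.10. MIR5642a rose by 3.17 ± 0.45 (edgeR adjusted p = 1.46e-05), MIR5642b by 2.91 ± 0.59, MIR167A by 1.13 ± 0.33, MIR5657 by 1.33 ± 0.41, MIR2936 by 1.32 ± 0.32 and MIR5635a by 1.15 ± 0.38. MIR5642a and MIR5642b share a mature sequence, so their counts cannot be fully told apart. The same holds for other named loci, among them MIR156C, MIR156E and MIR156F, MIR390A and MIR390B, MIR166A and MIR166B, and MIR167A and MIR167B. Changes of such copies are changes of locus counts, not of separate mature miRNAs. MIR167B was called at 1.58 ± 0.45 with values of −0.22, 3.24 and 1.71 in the wild type, xpf-3 and uvr8-6.

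Smaller increases were measured for MIR158A (0.68 ± 0.16), MIR390A (0.67 ± 0.13), MIR403 (0.67 ± 0.17), MIR160A (0.57 ± 0.17), MIR161 (0.48 ± 0.13), MIR156C (0.36 ± 0.10) and MIR159B (0.29 ± 0.11), and for MIR775A, MIR829A and MIR8176 (0.57 ± 0.21, 0.57 ± 0.18 and 0.54 ± 0.16), all past edgeR's threshold over n = 9 libraries per condition. These 10 turned negative with the library sizes of the table of all small RNAs, which shifted the median by −0.73, gave 3 higher and 44 lower miRNAs, and called MIR156C and MIR159B lower. With no low-count filter 27 were called, 5 higher and 22 lower. MIR166G was also called, from low counts that were 0 in dark wild type.

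**Figure D1:**
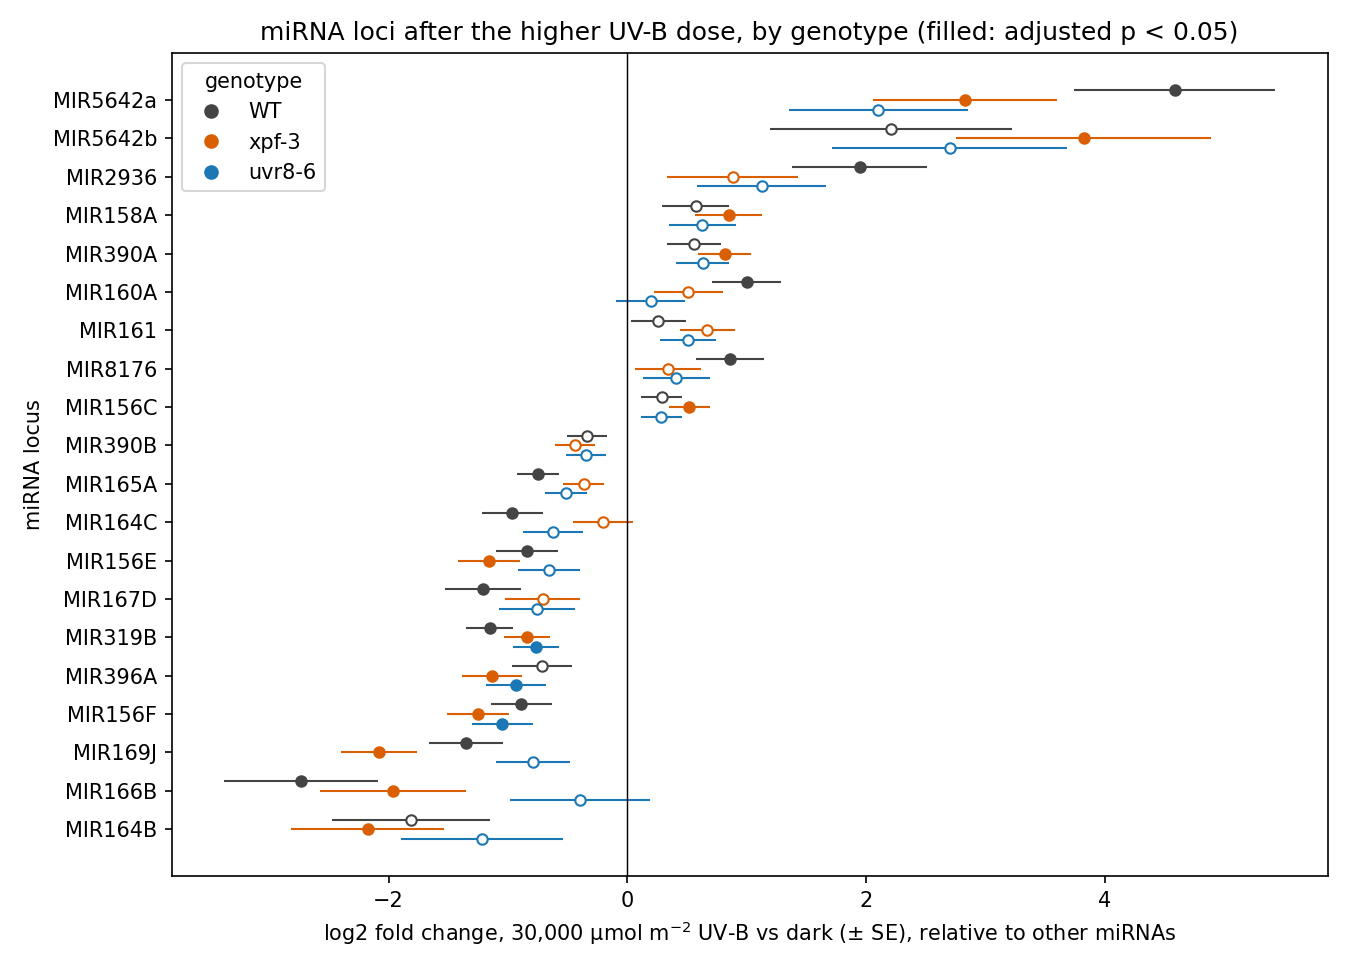
Log2 fold change after 30000 µmol per square metre UV-B (30K) against dark for 20 miRNA loci in the wild type, xpf-3 and uvr8-6 (points, edgeR estimate; bars, SE; n = 3 libraries per group; filled points, edgeR adjusted p under 0.05). The loci were picked for the plot after their values were seen; MIR319B lay at −1.15, −0.84 and −0.76 in the 3 genotypes, while the values above 0 of MIR158A, MIR390A, MIR160A, MIR161, MIR8176 and MIR156C turned negative in the mean of genotypes with the library sizes of all small RNAs.

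The lower dose changed fewer miRNAs. MIR167D (AT1G31173) fell by 1.39 ± 0.32 in the wild type (edgeR adjusted p = 0.023, n = 3 per group), from 12003 to 4564 CPM, and was the single call there, beside 5 at an unadjusted p under 0.05. In xpf-3 MIR167D fell by 1.43 ± 0.32, MIR396A by 1.33 ± 0.25 (edgeR adjusted p = 0.00283), MIR171B by 1.79 ± 0.54, MIR156E by 0.91 ± 0.26 and MIR160C by 0.62 ± 0.16, while MIR160A and MIR167A rose by 1.21 ± 0.29 and 2.05 ± 0.61. These were the 7 calls of that genotype, with 24 at an unadjusted p under 0.05. In uvr8-6 edgeR called 0 miRNAs, with 5 at an unadjusted p under 0.05 and 0 by DESeq2, and MIR167D stood at −1.04 ± 0.32 (edgeR adjusted p = 0.378). Over the 3 genotypes MIR167D fell by 1.29 ± 0.18 (edgeR adjusted p = 5.55e-05, n = 9 per condition), MIR396A by 0.69 ± 0.14 and MIR160C (AT5G46845) by 0.50 ± 0.09. The call in the wild type was lost (0 miRNAs) without dark replicate II or without any 1 of the 3 treated replicates. In xpf-3 the count was 3 without treated replicate I and 11 without dark replicate II, 17 (5 higher, 12 lower) with DESeq2, 13 with no low-count filter (1 higher, 12 lower) and 16, all lower, with the library sizes of all small RNAs. The 3 calls of the mean became 13 with DESeq2 (6 higher, 7 lower) and 12 with those library sizes (1 higher, 11 lower), and 15 of 18 fits that left out 1 library gave 5 to 12.

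Whether the mutants responded to UV-B otherwise than the wild type was tested as an interaction. For xpf-3 edgeR called 0 miRNAs at the lower dose and 0 at the higher dose, with 4 and 8 at an unadjusted p under 0.05 and 0 by DESeq2 at each. For uvr8-6 it called 0 and 0, with 3 and 9 at an unadjusted p under 0.05 and 0 by DESeq2 at each. Tested as lists in either direction, limma fry passed predicted UV-B-induced and NF-Y and drought in the xpf-3 interaction at the higher dose (adjusted p = 0.00378 and 0.0196) and predicted UV-B-induced in that of uvr8-6 (adjusted p = 0.0293), while camera passed none. Predicted UV-B-induced holds 51 of the 101 tested miRNAs, among them all 14 of NF-Y and drought. For single loci, the differences above between genotypes in the number of calls are not shown to be differences in response. With the loci of a family summed, a reading added after the data had been seen, 1 of 55 families passed. The MIR167 sum, whose products target auxin response factors, went from 14809 ± 2097 CPM (SD, n = 3) in dark wild type to 6628 ± 1049 after the lower and 6822 ± 846 after the higher dose, and in uvr8-6 from 12642 ± 668 to 12739 ± 1854 and 13386 ± 3025. The uvr8-6 interaction was 1.17 ± 0.27 at the lower dose (edgeR adjusted p = 0.0118) and 1.20 ± 0.27 at the higher dose (edgeR adjusted p = 0.00952), and no single MIR167 locus passed it. The lower-dose call was lost with DESeq2 (adjusted p = 0.0642), with the library sizes of all small RNAs (edgeR adjusted p = 0.382) and in 10 of 12 edgeR fits that left out 1 library (adjusted p up to 0.302). Both doses share their dark libraries. The interaction values with the smallest p at the higher dose were those of MIR399C in xpf-3 (−3.08 ± 0.99, edgeR adjusted p = 0.212) and MIR166B in uvr8-6 (2.34 ± 0.86, edgeR adjusted p = 0.42), besides MIR169N, MIR169E and MIR167B. On simulated data of the same depth the uvr8-6 interaction at the higher dose recovered 14.3% of 2-fold and 59.7% of 4-fold changes among 101 miRNAs. Across the 101 miRNAs, which are not independent replicates, the higher-dose changes of xpf-3 and uvr8-6 correlated with Pearson's r = 0.0609 and Spearman's rho = 0.565, and with r = 0.685 over the 93 miRNAs of at least 100 CPM. For the wild type the corresponding values were 0.217, 0.412 and 0.202 with xpf-3, and 0.0742, 0.387 and 0.341 with uvr8-6. The same direction was seen in 74.3% of miRNAs for xpf-3 and uvr8-6, 69.3% for the wild type and xpf-3, and 67.3% for the wild type and uvr8-6. At the lower dose r was 0.427 for the wild type and xpf-3 (65.3% in the same direction, r = 0.535 over the 93 miRNAs), −0.0420 for the wild type and uvr8-6 (46.5%, −0.234) and −0.271 for xpf-3 and uvr8-6 (57.4%, −0.232).

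Dark uvr8-6 hypocotyls differed from dark wild-type hypocotyls. MIR472A (AT1G12294), whose family targets resistance genes of the NBS-LRR type, was higher by 1.73 ± 0.31 (edgeR adjusted p = 0.00165, n = 3 per group), at 4079 against 1221 CPM. MIR167A was higher by 2.01 ± 0.58, MIR390A and MIR390B by 0.92 ± 0.22 and 0.61 ± 0.17, MIR156C by 0.73 ± 0.17, MIR846A by 0.95 ± 0.29 and MIR8175 by 1.20 ± 0.33. MIR2939 had 25 counts against 1, a ratio of 36.6 with a 95% exact counting interval of 5.98 to 1501. MIR822A (AT5G03552) was lower by a log2 value of −1.03 ± 0.21 (edgeR adjusted p = 0.00357), at 29200 ± 4840 against 59466 ± 4518 CPM (SD). MIR396A had 60228 ± 22410 against 120802 ± 12047 CPM (SD), MIR396B stood at −1.19 ± 0.33, MIR167D at −1.18 ± 0.32, MIR399B at −1.05 ± 0.33, MIR169M at −0.99 ± 0.32 and MIR166A at −0.78 ± 0.24. The 15 called miRNAs were 8 higher and 7 lower in uvr8-6, with 30 at an unadjusted p under 0.05, and the libraries of the 2 groups did not overlap in any of them (24.8% of tested miRNAs, 10% by chance). With the library sizes of all small RNAs 12 were called (2 higher, 10 lower), with no low-count filter 9 (2 higher, 7 lower), when only the groups compared were fitted 2, without wild-type dark replicate II 8 and without dark replicate III 9.

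A comparison of the mutants with the wild type over the 3 doses was added after the data had been seen. Over 9 libraries per genotype edgeR called 44 miRNAs between uvr8-6 and the wild type, 20 higher and 24 lower in uvr8-6, with 50 at an unadjusted p under 0.05. MIR472A was higher by 1.78 ± 0.18 (edgeR adjusted p = 2.32e-07), with 3118 to 7327 CPM in the 9 uvr8-6 libraries and 780 to 1719 in the 9 wild-type libraries. MIR822A stood at −1.14 ± 0.12 (edgeR adjusted p = 2.32e-07), with 15848 to 34380 against 47412 to 64663 CPM. MIR396B and MIR169M stood at −1.50 ± 0.19 and −1.40 ± 0.19, and MIR167A, MIR390B, MIR8175 and MIR846A at 2.31 ± 0.34, 0.62 ± 0.10, 1.06 ± 0.19 and 0.85 ± 0.17, each with no overlap between the libraries of the genotypes. The library sizes of all small RNAs gave 36 calls, 12 higher and 24 lower.

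**Figure D2:**
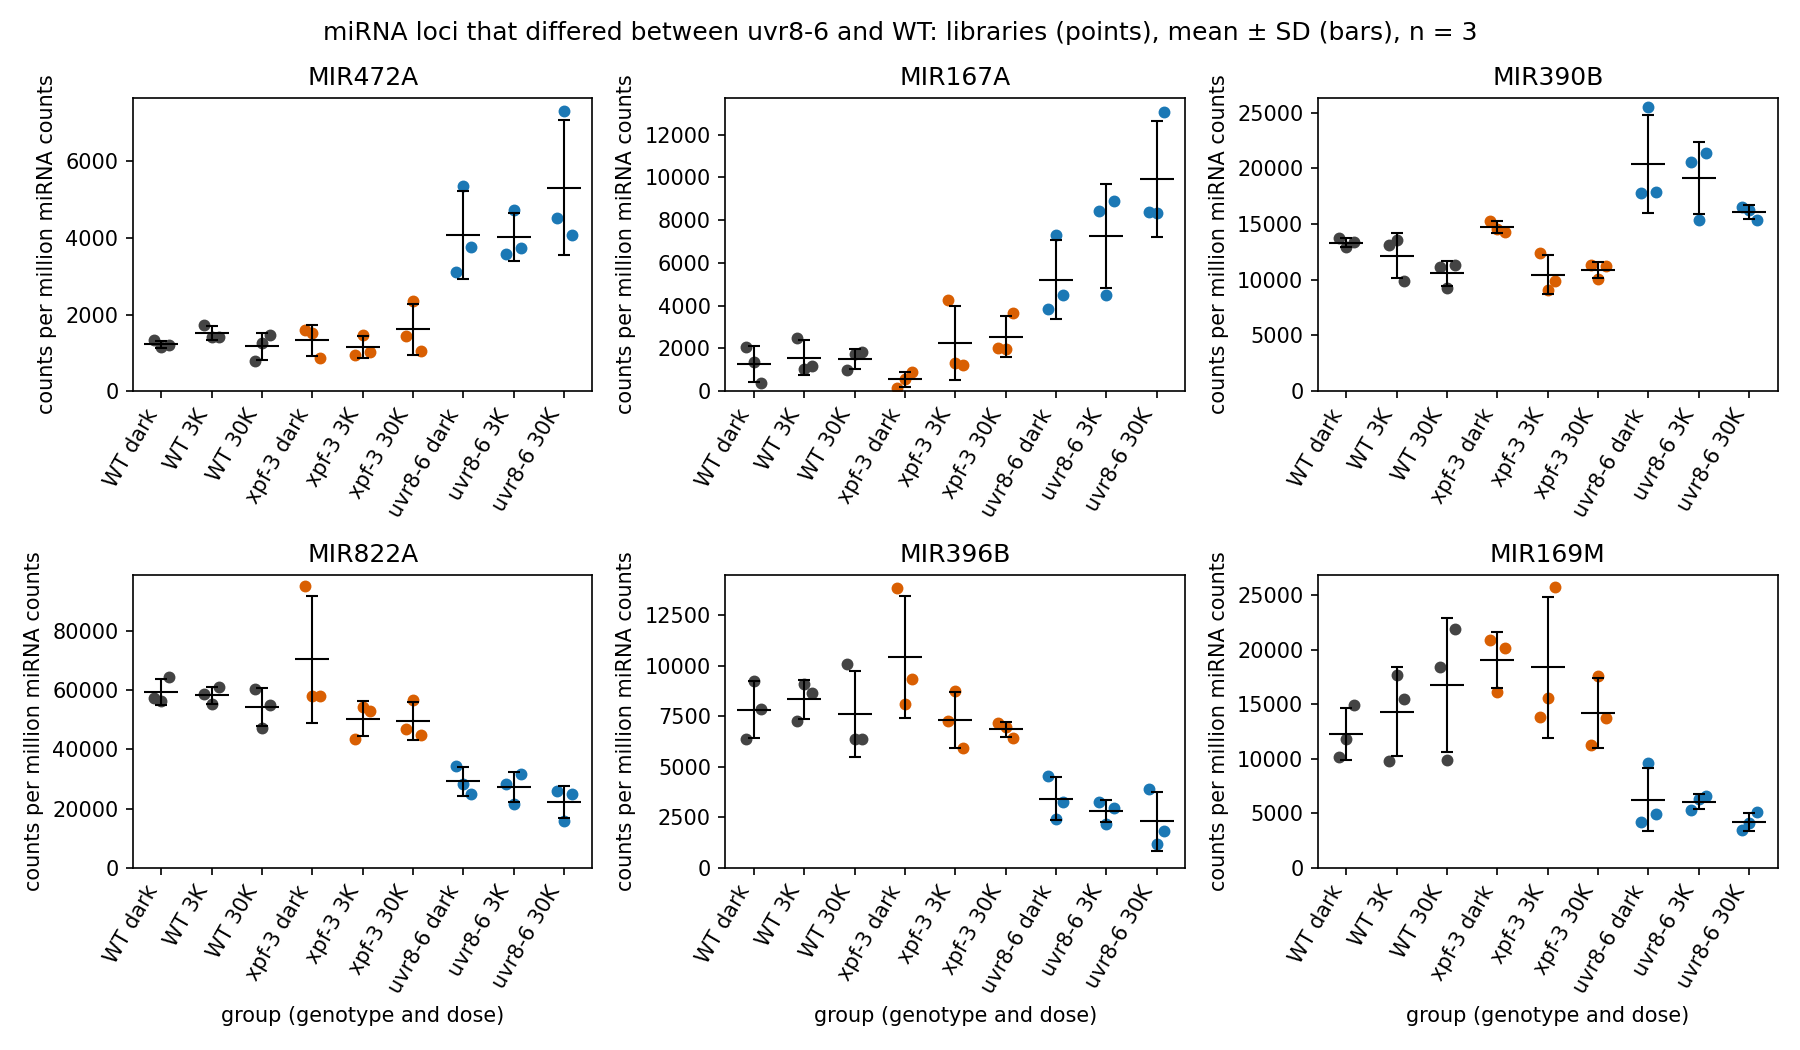
CPM, per miRNA total times TMM factor, of MIR472A, MIR167A, MIR390B, MIR822A, MIR396B and MIR169M in each of the 27 libraries, by genotype and dose (points, libraries, and lines, means of 3). The loci were picked for the plot after their values were seen; MIR472A lay at 3118 to 7327 in uvr8-6 and at 780 to 1719 in the wild type.

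Dark xpf-3 hypocotyls gave 0 called miRNAs against the dark wild type with edgeR, 5 at an unadjusted p under 0.05 and 0 with DESeq2. The smallest p-values belonged to MIR399C (2.37 ± 0.72, edgeR adjusted p = 0.356) and MIR408 (1.48 ± 0.52, edgeR adjusted p = 0.445), n = 3 per group. This MIR399C value, its rise in the wild type and its xpf-3 interaction share the dark wild-type libraries, so they are not separate results. Over the 3 doses 2 miRNAs were called, MIR408 (AT2G47015), which targets transcripts of copper proteins, at 1.61 ± 0.30 (edgeR adjusted p = 0.00248, n = 9 per genotype) and MIR8175 at 0.82 ± 0.19 (edgeR adjusted p = 0.0157), with 10 at an unadjusted p under 0.05. Both were also called higher in uvr8-6 against the same wild-type libraries, MIR408 at 1.15 ± 0.30 (edgeR adjusted p = 0.00384) and MIR8175 as given above. They are therefore not particular to xpf-3. MIR408 had 207 counts in the 9 xpf-3 libraries, 140 in those of uvr8-6 and 78 in those of the wild type. The count of xpf-3 calls was 0 with the library sizes of all small RNAs, and 14 of 18 fits that left out 1 library gave 1.

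The miRNAs were grouped by 12 lists fixed before the data were examined. After the higher dose, over the 3 genotypes, growth transcription factors (families targeting MYB, HD-ZIP III, GRAS, TCP and growth-regulating factor genes) had 2 members higher and 7 lower of 19 tested, and 3 and 8 adjusted over the list alone. The lower members included MIR319B, MIR396A and MIR165A, and camera gave an adjusted p of 0.055. Phase change (miR156, miR157, miR172) had 1 higher, MIR156C, and 2 lower, MIR156E and MIR156F, of 12. Auxin signalling had 4 higher (MIR160A, MIR167A, MIR167B, MIR390A) and 5 lower (MIR164B, MIR164C, MIR167C, MIR167D, MIR390B) of 13. In these lists MIR156C, MIR156E and MIR156F share a mature sequence, as do MIR390A and MIR390B, so their opposite calls are not of separate mature miRNAs. The predicted UV-B-induced list, recalled from a published computational prediction, had 6 higher and 11 lower of 51, and camera placed it lower than other miRNAs (adjusted p = 0.0217), a call not kept with adjusted p = 0.131 with an estimated correlation. Its median log2 change was −0.05 and its mean 0.01. Triggers of secondary siRNAs had 2 higher and 1 lower of 7 (3 and 1 adjusted over the list alone), miRNA machinery 1 higher (MIR403) of 5, NF-Y and drought 1 lower (MIR169J) of 14, and other organs than the hypocotyl 2 lower (MIR164B, MIR164C) of 7. Copper (1 tested), phosphate and sulfate (2), MYB of the phenylpropanoid pathway (1) and light-regulated (3) had 0 called. For this comparison, counts adjusted over the list alone equalled those over all miRNAs where no other value is given. The fry test, which asks whether members changed on values scaled to the miRNA counts, placed growth transcription factors, predicted UV-B-induced, NF-Y and drought, and other organs lower (fry adjusted p = 0.00298, 0.0036, 0.0204 and 0.0163) and triggers of secondary siRNAs and miRNA machinery higher (fry adjusted p = 0.0163 and 0.0224). The called higher members of the lists placed higher (MIR390A, MIR161 and MIR403) turned negative with the library sizes of all small RNAs. The fry test was not repeated with those library sizes. With members summed by family, camera called growth transcription factors, predicted UV-B-induced and auxin signalling lower (adjusted p = 0.0166, 0.0406 and 0.048).

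In uvr8-6 after the higher dose camera placed the predicted UV-B-induced list (0 higher, 2 lower of 51) and the growth transcription factors (0 higher, 2 lower of 19, and 0 and 3 adjusted over the list alone) below other miRNAs, with adjusted p = 0.0315 and 0.0345 (camera on the edgeR fit, 3 libraries per group). Both calls were lost in camera, at adjusted p = 0.174 with an estimated correlation and adjusted p = 0.253 with an estimated correlation. Camera called no other list in any of the 14 comparisons, 3 calls in 126 tests. With members summed by family it gave 9, which kept growth transcription factors in uvr8-6 and not predicted UV-B-induced (camera on the edgeR fit, adjusted p = 0.00239 and 0.139). The others among these 9, all lower, were auxin signalling in the wild type at the lower and higher dose and in the mean at the lower dose, and growth transcription factors and predicted UV-B-induced in the wild type at the higher dose, besides the 3 in the mean at the higher dose. The fry test gave 11 calls in a common direction and 34 in either direction. Besides the 6 in the mean at the higher dose, those in a common direction were other organs lower in xpf-3 at the higher dose (limma fry adjusted p = 0.0376), and 4 in dark uvr8-6. In dark uvr8-6 miRNA machinery, growth transcription factors and other organs were lower and triggers of secondary siRNAs higher (limma fry adjusted p = 0.00759, 0.048, 0.00833 and 0.00833). After the higher dose, miRNA machinery adjusted over the list alone had 1 higher of 5 in uvr8-6 against its own dark libraries. Phase change had 1 lower of 12 in that comparison. The counts given next for the wild type and xpf-3 are also those after the higher dose, until the lower dose is named. In the wild type the predicted UV-B-induced list had 1 higher and 9 lower of 51, growth transcription factors had 4 lower of 19 (1 higher and 5 lower adjusted over the list alone), auxin signalling 1 higher and 2 lower of 13 (1 and 3), phase change 2 lower of 12, NF-Y and drought 2 lower of 14, phosphate and sulfate 1 higher of 2, and other organs than the hypocotyl 1 lower of 7 (2). In xpf-3 the predicted UV-B-induced list had 3 higher and 5 lower, auxin signalling 3 and 1 (3 and 2), growth transcription factors 0 and 3, phase change 1 and 2, miRNA machinery 1 and 0, triggers of secondary siRNAs 1 and 0 (2 and 1), NF-Y and drought 0 and 1, and other organs 0 and 1. At the lower dose the xpf-3 counts were 2 higher and 2 lower for auxin signalling (4 and 4), 2 and 4 for predicted UV-B-induced, 0 and 2 for growth transcription factors (0 and 3) and 0 and 1 for phase change. In the mean they were 0 and 2 for auxin signalling (3 and 4), 0 and 2 for predicted UV-B-induced (0 and 3), 0 and 1 for growth transcription factors and 0 for NF-Y and drought (0 and 1). The wild type had 1 lower in auxin signalling (2) and 1 in predicted UV-B-induced, and uvr8-6 had 0 (1 lower in auxin signalling and 1 in MYB of the phenylpropanoid pathway adjusted over the list alone). Between dark uvr8-6 and dark wild type, triggers of secondary siRNAs had 3 higher (MIR390A, MIR390B, MIR472A) of 7, auxin signalling 3 higher and 1 lower of 13 and growth transcription factors 3 lower (MIR166A, MIR396A, MIR396B) of 19, and the smallest camera adjusted p on the edgeR fit was 0.276. Of the other lists, phase change had 1 higher, phosphate and sulfate 1 lower, predicted UV-B-induced 2 higher and 3 lower (2 and 2 adjusted over the list alone), NF-Y and drought 1 lower (0 adjusted over the list alone), and miRNA machinery 0 (1 lower adjusted over the list alone). In dark xpf-3 copper, phosphate and sulfate, and light-regulated had 0 called and 1 higher each adjusted over the list alone. The interactions had 0 called in each list, and adjusted over the list alone 1 lower in phosphate and sulfate and 1 higher in NF-Y and drought for xpf-3 at the higher dose, and 1 lower in MYB of the phenylpropanoid pathway for uvr8-6 at each dose.

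The classes of small RNA were compared as shares of all counts. After the higher dose the miRNA share over the 3 genotypes was 2.79% ± 0.782 against 4.13% ± 1.33 in the dark (SD within groups, n = 9 per condition), and the difference of −1.34 points passed an exact permutation test within genotype (p = 0.0165, adjusted p = 0.0413). The snoRNA share was 4.91% ± 0.993 against 3.70% ± 0.782, a difference of 1.21 points (exact permutation p = 0.0135, adjusted p = 0.0413). rRNA, tRNA and snRNA differed by 2.33, −2.17 and −0.0352 points and did not pass (exact permutation adjusted p = 0.113, 0.121 and 0.868). Within a genotype 3 libraries against 3 cannot give an exact p under 0.1. Each of the 2 calls was lost in 15 of 18 tests that left out 1 library, with differences of −1.67 to −1.12 points for miRNA and 1.01 to 1.42 for snoRNA. At the lower dose 0 of 5 shares passed, and the largest difference was that of rRNA at 2.78 points (exact permutation p = 0.0363, adjusted p = 0.111). Over the 3 doses, a test added after the data had been seen, uvr8-6 had 4.81 points more rRNA than the wild type (exact permutation p = 0.00025, the smallest this design can give, adjusted p = 0.00125, n = 9). It had 0.884 points more snoRNA, and −0.862, −3.71 and −1.12 points of snRNA, tRNA and miRNA (exact permutation adjusted p = 0.043, 0.00125, 0.00167 and 0.0303). In xpf-3 0 of 5 shares passed (smallest exact permutation adjusted p = 0.604).

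**Figure D3:**
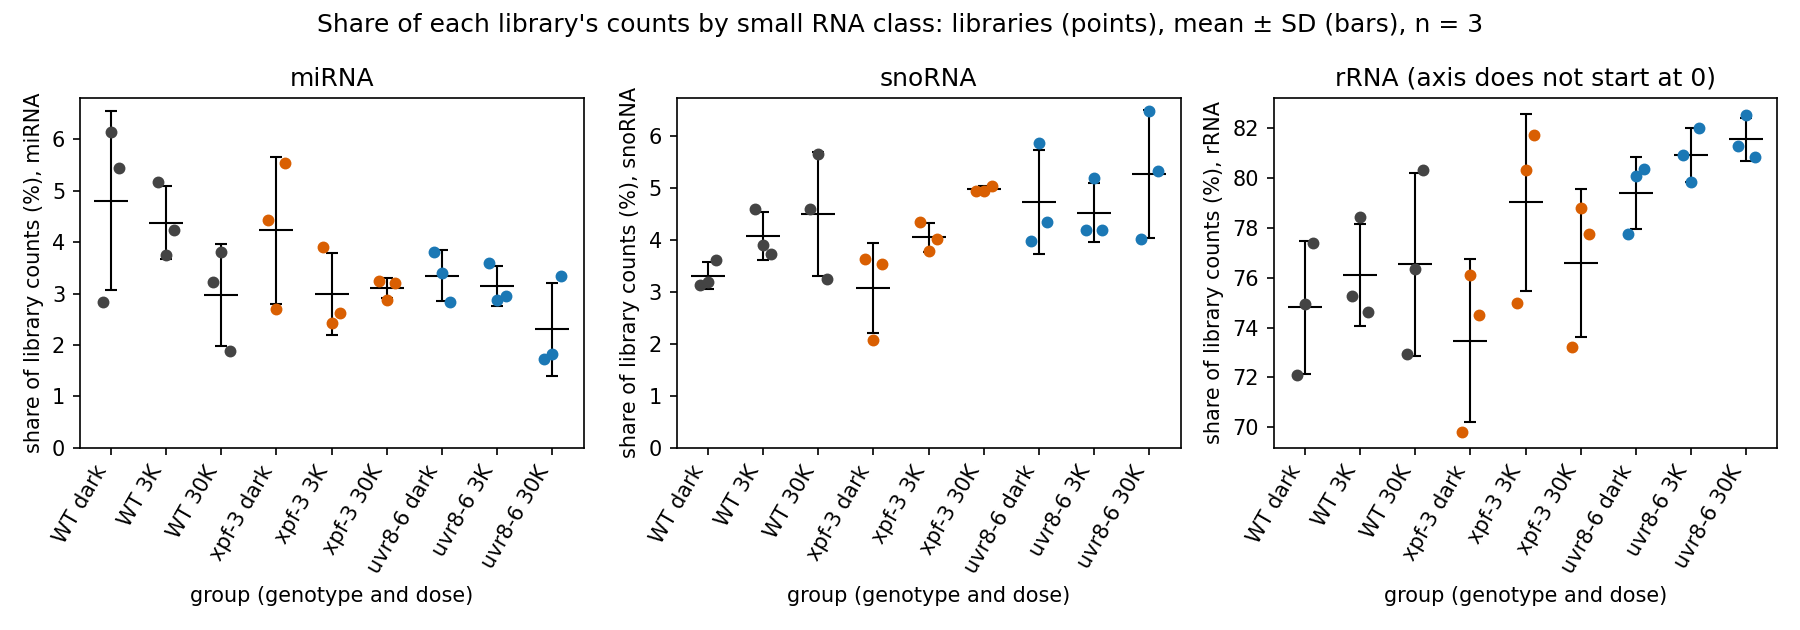
Share of all small RNA counts (percent) from miRNA, snoRNA and rRNA loci in each of the 27 libraries, by genotype and dose (points, libraries; bars, mean ± SD, n = 3); the rRNA axis does not start at 0. Over the 3 genotypes the miRNA share averaged 4.13% in the dark and 2.79% after the higher dose, and the snoRNA share 3.70% and 4.91%.

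Over all 1109 tested small RNA loci the higher dose changed 187 in the mean of the 3 genotypes, 88 higher and 99 lower, with 340 at an unadjusted p under 0.05. Of 318 snoRNAs, guides of rRNA modification, 52 were higher and 5 lower. Of 101 miRNAs 3 were higher and 33 lower, of 97 snRNAs 4 and 20, of 481 tRNA loci 29 and 26 and of 112 rRNA loci 0 and 15. These counts include near-identical loci, so they are not counts of separate signals. Among all deposited loci 99 were near-identical to another, 54 of them snoRNA and 33 snRNA. The lower rRNA loci stand beside an rRNA share that was 2.33 points higher, a difference that did not pass. tRNA-Arg AT5G65535 fell by 1.40 ± 0.21 (edgeR adjusted p = 0.000168, n = 9 per condition), tRNA-Lys AT3G56085 rose by 2.76 ± 0.57 and tRNA-Trp AT1G15450 by 1.11 ± 0.23. DESeq2 called 286, and with near-identical loci kept once the calls were 167, 99 higher and 68 lower. In the wild type 21 loci were called (5 higher, 16 lower; 169 at an unadjusted p under 0.05). Of the lower loci 15 were miRNAs and 1 rRNA, and of the higher loci 3 were snoRNAs, 1 a miRNA and 1 a tRNA locus. They included the snoRNAs AT3G08165 (1.40 ± 0.35) and AT5G02305 (0.91 ± 0.20), and DESeq2 called 111 (51 higher, 60 lower). In xpf-3 54 were called (12 higher, 42 lower; 224 unadjusted). The lower loci were 19 miRNAs, 9 snRNAs, 7 rRNA and 7 tRNA loci, and the higher ones 8 snoRNAs and 4 tRNA loci, with snoRNAs AT3G01316 (1.06 ± 0.30) and SNOR108 (0.95 ± 0.24), tRNA-Lys AT3G56085 (4.54 ± 1.08) and tRNA-Arg AT5G65535 (−2.60 ± 0.38, edgeR adjusted p = 0.000707, n = 3 per group). DESeq2 gave 171 (83 higher, 88 lower), near-identical loci kept once 37 (18 higher, 19 lower) and rRNA left out 45 (15 higher, 30 lower). In uvr8-6 6 were called (3 higher, 3 lower; 114 unadjusted), with 2 miRNAs among the lower and tRNA-Pro AT2G33950 (2.29 ± 0.44) among the higher. When only the groups compared were fitted, which also left fewer loci and samples (837, 948 and 843 loci tested), these counts were 2, 0 and 1, and leaving out 1 library gave 5 (wild type, higher-dose replicate I) to 37 (dark replicate I), 11 (xpf-3, higher-dose replicate III) to 29 (dark replicate III) and 0 (uvr8-6, dark replicate I or higher-dose replicate I) to 11 (dark replicate III).

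At the lower dose 0 small RNA loci were called in the wild type (67 at an unadjusted p under 0.05 with edgeR, 26 called by DESeq2) and 0 in uvr8-6 (56 and 26). In xpf-3 6 were lower (163 at an unadjusted p under 0.05), among them MIR396A (−1.97 ± 0.33, edgeR adjusted p = 0.0109, n = 3 per group) and the tRNA locus ENSRNA049492746 (−1.28 ± 0.27). DESeq2 called 87 there (35 higher, 52 lower), and leaving out 1 library gave 0 to 4. Over the genotypes 10 were called (2 higher, 8 lower; DESeq2 107, 45 higher and 62 lower), among them snoRNA AT3G04155 (0.62 ± 0.14) and tRNA-Arg AT5G65535 (−0.95 ± 0.21), and 1 without uvr8-6 treated replicate II. The interactions gave 0 calls for xpf-3 (53 and 52 at an unadjusted p under 0.05 with edgeR at the lower and higher dose, 19 and 18 called by DESeq2) and 0 for uvr8-6 (57 and 62, DESeq2 32 and 28). Dark xpf-3 gave 0 calls against the dark wild type (52 at an unadjusted p under 0.05 with edgeR, 24 called by DESeq2).

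Dark uvr8-6 differed from dark wild type in 129 small RNA loci, 53 higher and 76 lower, with 283 at an unadjusted p under 0.05. The snoRNA AT2G08760 was higher by 2.16 ± 0.28 (edgeR adjusted p = 0.000164, n = 3 per group), tRNA-Met AT2G33140 by 2.48 ± 0.69 and tRNA-His AT3G06665 by 2.38 ± 0.65. tRNA-Pro AT2G33950 stood at −4.12 ± 0.47 (edgeR adjusted p = 3.64e-05), and tRNA-Glu AT2G38030 had 0 counts against 591, at least 164-fold lower. Of 318 snoRNAs 37 were higher and 13 lower, of 97 snRNAs 0 and 16, of 112 rRNA loci 0 and 16, of 101 miRNAs 2 and 9 and of 481 tRNA loci 14 and 22. These class counts also include near-identical loci. The rRNA share was 4.59 points higher in dark uvr8-6 (exact permutation p = 0.1). DESeq2 called 231, and 120 were called with rRNA left out (64 higher, 56 lower). The count was 0 when only the groups compared were fitted, 31 without uvr8-6 dark replicate II, 77 without uvr8-6 dark replicate III and 53 without wild-type dark replicate I. Over the 3 doses edgeR called 338 loci between uvr8-6 and the wild type (159 higher, 179 lower, n = 9), with the smallest p for AT2G08760 (2.15 ± 0.16), the snoRNA AT2G08770 (1.43 ± 0.12) and tRNA-Pro AT2G33950 (−2.97 ± 0.26), and 0 between xpf-3 and the wild type (87 at an unadjusted p under 0.05, 21 called by DESeq2).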

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

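The test of the MIR167 family was chosen after its result was seen. The response of the summed MIR167 counts to UV-B differed between uvr8-6 and the wild type by 1.17 at the lower dose and 1.20 at the higher dose on the log2 scale (edgeR interaction on family sums, adjusted p = 0.0118 and 0.00952, 3 libraries per group). This is a difference between genotypes in the sum, found by a test of the difference itself, and it was not shown for any locus. The wild-type sum decreased by 1.16 ± 0.19 and 1.11 ± 0.19, and the uvr8-6 sum stood at 0.01 ± 0.19 and 0.09 ± 0.19. At the higher dose the interaction was called in each of 12 fits that left out 1 library (1.20 to 1.61) and with each other setting. At the lower dose it was called in 2 of 12 (0.90 to 1.21), and not with DESeq2 (adjusted p = 0.0642) or with the library sizes of all small RNAs (edgeR adjusted p = 0.382). No MIR167 locus passed alone: MIR167A, MIR167B, MIR167C and MIR167D stood at 0.70 ± 0.80, 1.93 ± 1.08, 0.08 ± 1.04 and 0.45 ± 0.45 at the higher dose, and at 0.18 ± 0.79, 0.98 ± 1.05, 0.11 ± 0.85 and 0.35 ± 0.45 at the lower dose, each below the value of the sum there. MIR167A was the more abundant in dark uvr8-6, at 5218 against 1268 CPM, and MIR167D the less, at 5261 against 12003 CPM. Sums of such different mixes can differ in response when the loci do not, so the sums alone do not show a different response to UV-B. Whether this different mix of loci accounts for the difference between the sums was not tested. No biological explanation was tested.

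Limma fry in either direction passed lists in the interactions at the higher dose, with 3 libraries per group. In xpf-3 these were predicted UV-B-induced (fry adjusted p = 0.00378) and NF-Y and drought (fry adjusted p = 0.0196). In uvr8-6 it was predicted UV-B-induced (fry adjusted p = 0.0293). The test asks whether members changed, not whether they changed more than other miRNAs, and gave 34 calls in 126 tests. Predicted UV-B-induced holds all 14 members of NF-Y and drought, so the 2 are not separate results. Some of these 14 had few counts, such as MIR169D and MIR169E with means of 2 and 1.78 per library. Others had many, such as MIR169C with 5097. Camera called 0 lists in these interactions, and no locus passed alone. The fry test was fixed before the data were examined.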

How the results depend on the processing

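The tests that keep near-identical loci once or leave out rRNA, and every test over the 3 doses, were chosen after the results were seen, and the other settings before the data were examined. Of 91 named miRNA changes, 90 stayed past the threshold with DESeq2, 90 with RLE factors, 64 with no low-count filter, 85 with the replicate block, 67 of 89 with only the groups compared and 60 with the library sizes of all small RNAs, where 18 were lost and 13 reversed. When libraries were left out in turn, 52 were lost at least once and 0 reversed. Of 88 named changes among all small RNAs the numbers kept were 88, 86, 60 and 78, 35 of 87 with only the groups compared, 82 of 86 with near-identical loci once and 85 of 85 without rRNA, and 55 were lost at least once. With DESeq2 the miRNA counts were 17 (xpf-3 lower dose, 7 in edgeR), 28 (xpf-3 higher dose, 16) and 13 (mean lower dose, 3). For all small RNAs DESeq2 gave 26 and 111 (wild type, lower and higher dose), 87 and 171 (xpf-3), 26 and 52 (uvr8-6), 107 and 286 (means), 24 and 231 (dark xpf-3 and uvr8-6 against wild type), 19 and 18 (xpf-3 interactions), 32 and 28 (uvr8-6 interactions) and 21 (xpf-3 over the doses). With no low-count filter the miRNA counts were 13 (xpf-3 lower dose), 7 (mean lower dose) and 9 (dark uvr8-6), and for all small RNAs 9 (wild type higher dose), 1 and 23 (xpf-3) and 5 (mean lower dose). With only the groups compared they were 13 (xpf-3 lower dose), 1 (uvr8-6 higher dose) and 2 (dark uvr8-6) for miRNAs, and for all small RNAs 2 (wild type higher dose), 0 and 0 (xpf-3), 1 (uvr8-6 higher dose), 1 (dark xpf-3), 0 (dark uvr8-6) and 1 (uvr8-6 interaction, higher dose); these fits have fewer samples. With near-identical loci kept once, 1 locus was called in xpf-3 and 1 in uvr8-6 at the lower dose. With the library sizes of all small RNAs the miRNA counts were 28 (wild type higher dose), 16 and 33 (xpf-3), 12 (mean lower dose) and 0 (xpf-3 over the doses). The list tests gave 0 calls with an estimated correlation and 9 with members summed by family, against 3. Over miRNAs of at least 100 CPM, r at the higher dose was 0.341 for the wild type and uvr8-6 and 0.685 for xpf-3 and uvr8-6, against 0.0742 and 0.0609. Apart from the fits with fewer samples or loci, the cause was not tested.

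The library sizes of all small RNAs are totals times TMM factors. They shifted the median miRNA by −0.73 in the mean at the higher dose, where the log2 miRNA share changed by −0.56. The shift is therefore not the fall of the share alone, and whether the smallest reversals depend on the factors was not tested. Values reversed for MIR8176 (−0.076), MIR169C (−0.29), MIR158A (−0.34), MIR169A (−0.75), MIR8175 (−0.77) and MIR156C (−0.68) in the wild type at the higher dose. They did so for MIR390A (−0.057) and MIR156C (−0.32) in xpf-3. In the mean they did so for MIR158A (−0.072), MIR390A (−0.044), MIR403 (−0.084), MIR775A (−0.18), MIR160A (−0.18), MIR829A (−0.15), MIR8176 (−0.19), MIR161 (−0.25), MIR159B (−0.45) and MIR156C (−0.39). With no low-count filter MIR169A (−0.14) and MIR8175 (−0.041) reversed in the wild type. Leaving out 1 library, values not called in the wild type reversed for MIR158A without higher-dose replicate II (−0.013, range to 0.71), for MIR169A without dark replicates I (−0.078) and II (−0.48) or without higher-dose replicates I (−0.22), II (−0.029) and III (−0.030), and for MIR169B without higher-dose replicate I (0.11, range from −0.77). They also did so for MIR8175 without dark replicates I (−0.30) and III (−0.11) or higher-dose replicate II (−0.28), with a range to 0.40, and for MIR156C without dark replicate I (−0.15) and higher-dose replicate II (−0.14), with a range to 0.35. The snRNA share difference in the mean at the higher dose, −0.0352 points, was 0.210 without the most abundant locus, and leaving out 1 library gave −0.135 to 0.0921, with 0.0672, 0.0655, 0.0921, 0.00223 and 0.0150 above 0. The cause was not tested.

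Leaving out each library in turn gave these lowest and highest counts for miRNAs: 0 to 1 and 7 to 20 in the wild type (lower and higher dose), 3 to 11 and 8 to 12 in xpf-3, 0 to 0 and 0 to 5 in uvr8-6, 4 to 12 and 25 to 36 in the means, and 8 to 16 in dark uvr8-6. The interactions at the higher dose gave 0 to 1 for xpf-3 (1 without wild-type dark replicate III or higher-dose replicate II) and 0 to 1 for uvr8-6 (1 without wild-type higher-dose replicate II), and over the doses the ranges were 1 to 2 for xpf-3 and 40 to 45 for uvr8-6. For all small RNAs they were 5 to 37 (wild type higher dose), 0 to 4 and 11 to 29 (xpf-3), 0 to 11 (uvr8-6 higher dose), 1 to 15 and 137 to 213 (means), 31 to 100 (dark uvr8-6), 0 to 2 (uvr8-6 interaction, lower dose; 2 without wild-type dark replicate II) and 308 to 337 (uvr8-6 over the doses). The share differences ranged from −1.67 to −1.12 points for miRNA and 1.01 to 1.42 for snoRNA at the higher dose, each call being lost in 15 of 18 tests. The snoRNA share at the lower dose ranged from 0.342 to 0.699, and was called without uvr8-6 dark replicate II (exact permutation adjusted p = 0.0263). Agreement of the wild type and xpf-3 at the lower dose, 0.427, ranged from 0.114 to 0.386. These fits have fewer samples.

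The replicate numbers are shared between groups, but the labels do not say that a number marks a common batch. Over miRNAs, libraries of the same number had a mean correlation of −0.0124, against 0.00608 for other pairs (4 of 27 closest to their own number). Over all small RNAs the values were 0.0213 and −0.0107 (16 of 27), so a common batch is not excluded there. With the replicate block the counts for all small RNAs moved to 15 (xpf-3 lower dose, from 6) and 3 (uvr8-6 higher dose, from 6), and no other count moved by more than 1.5 times.

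Groupings of the same libraries were counted by whether they called as many loci as the real one, tests written down after the real counts had been seen, except those of miRNAs over the 3 doses. For 3 against 3 there are 10, too few for a share under 0.05. For miRNAs, 1 of 10 did so, the real one, in the wild type at the lower dose (1 called, highest other 0) and higher dose (15 and 1), in xpf-3 (7 and 1, 16 and 0), in uvr8-6 at the higher dose (3 and 1) and in dark uvr8-6 (15 and 1). For 0 calls, in uvr8-6 at the lower dose and in dark xpf-3, 10 of 10 did so, with highest others of 0 and 1. For all small RNAs 10 of 10 did so where 0 were called, 2 of 10 in the wild type at the higher dose (21, highest other 29), and 1 of 10, the real one, in xpf-3 (6 and 1, 54 and 0), in uvr8-6 at the higher dose (6 and 0) and in dark uvr8-6 (129 and 2). For the means 1 of 100 did so, the real one (3 and 2, 35 and 13 for miRNAs, and 10 and 2, 187 and 20 for all small RNAs), so chance is unlikely there. That is the lowest share that 100 draws can give, and 3 against 2 is a narrow margin. For the interactions 50 of 50 did so, which 0 real calls make certain, with highest others of 1, 2, 9 and 36 for miRNAs and 9, 42, 17 and 271 for all small RNAs. The groupings with 36 and 271 exchanged uvr8-6 and wild type in the dark libraries alone, which turns the interaction into the summed difference between these genotypes, and the highest of the rest were 17 and 7. The grouping of xpf-3 small RNAs with 42 is not of this kind, and its cause was not tested. Over the doses 1 of 100 did so for xpf-3 miRNAs (2 and 1), uvr8-6 miRNAs (44 and 30) and uvr8-6 small RNAs (338 and 126), and 100 of 100 for xpf-3 small RNAs (0 and 1). Where 1 of 100 did so chance is unlikely, though the margin of the xpf-3 miRNAs is narrow. The groupings over the doses were drawn again once, when all small RNAs were added, and the highest other for uvr8-6 miRNAs was several times lower in the first draw, so this value depends on the draw. Neither draw held another grouping with as many calls as the real one. How depth limits the number of calls was not tested on the libraries themselves. Wild-type replicate III after the higher dose has the fewest miRNA counts, 15790, and without it 7 miRNAs were called in place of 15, a fit with fewer samples, while on simulated data of the real depth edgeR recovered 39.7% of 2-fold changes in that comparison.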

Other observations

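With the loci of each miRNA family summed, 16 of 55 families were called after the higher dose in the mean of the 3 genotypes, 5 higher and 11 lower than other families (edgeR, n = 9 per condition). The MIR396 sum decreased by 1.11 ± 0.12 (edgeR adjusted p = 9.20e-08), MIR166 by 0.74 ± 0.10, MIR164 by 1.01 ± 0.14, MIR319 by 0.73 ± 0.11, MIR165 by 0.62 ± 0.13, MIR822 by 0.55 ± 0.09 and MIR156 by 0.39 ± 0.10. The MIR5642 sum rose by 2.97 ± 0.29 (edgeR adjusted p = 9.84e-09), MIR2936 by 1.13 ± 0.31 and MIR158, whose value for MIR158A turned negative with the library sizes of all small RNAs, by 0.46 ± 0.13. The sums in these 2 comparisons were not tested with those library sizes, which shifted the median miRNA by −0.73 after the higher dose and by −0.34 between dark uvr8-6 and dark wild type. In dark uvr8-6 10 families were called against the dark wild type, 7 higher and 3 lower, among them MIR472 (1.79 ± 0.33), MIR390 (0.74 ± 0.17), MIR822 (−0.97 ± 0.16) and MIR396 (−0.95 ± 0.21).

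The tests below were chosen after the results were seen. After the higher dose the miRNA share was lower and the snoRNA share higher. Dilution by rRNA was tested on the counts outside rRNA, where the snoRNA share, 23.1%, was 7.13 points above that in the dark (exact permutation p = 0.00625) and the miRNA share 12.7% against 17.2% (exact permutation p = 0.055), so dilution of all classes alike is excluded for the snoRNA share. Depth was tested by removing the slope of the log2 miRNA share on the log2 total, which left 0.846 of the difference (−0.47 of −0.56, exact permutation p = 0.0265), so depth is excluded as the whole cause. Differences in RNA breakdown or in size selection may remain, and were not tested, since fragment lengths were not used here, nor was a biological explanation.

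Copies of a miRNA with the same mature sequence moved apart after the higher dose. Of 26 such pairs with a mean of at least 100 counts for each copy, a minimum set after the values were seen, 14 changed in ratio (exact permutation, adjusted p under 0.05 over all 76 pairs), and 3 had copies called in opposite directions: MIR156C against MIR156E and MIR156F, and MIR390A against MIR390B. The MIR390A to MIR390B log2 ratio went from −1.71 to −0.65 (exact permutation p = 0.00025, the smallest possible). A fixed or random division of all reads of a pair would leave its ratio unchanged, which these 14 pairs argue against. For reads of the shared mature sequence alone the test cannot decide, since the locus counts also hold other fragments of each hairpin. Many of the pairs share a locus, such as MIR156E or MIR156F, so they are not independent. A further 7 pairs that changed in ratio hold a copy with too few counts to decide. Fragments outside the mature sequence may drive single copies, which was not tested, nor was a biological explanation.

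The 15 miRNAs called between dark uvr8-6 and dark wild type were looked up in the treated libraries, which are other samples. All 15 kept their sign at both doses, but another grouping of the treated libraries also reached 15, so this test was undecided. A test of size was then added: the mean signed difference was 1.30, the highest of the other groupings 0.986, and 1 of 200 groupings, the real one, was as large. Chance in the 6 dark libraries alone is therefore unlikely for the 15 as a set, but the mean does not decide it for each miRNA. Large differences weigh most in it, such as that of MIR2939, which had 1 count in the wild type over the 3 doses. Whether dark uvr8-6 resembles treated seedlings was tested by its correlation with the xpf-3 response to the higher dose, 0.355 against 0.317 in the highest of the other groupings (10 in all), which is undecided. A seed lot, growth or library batch shared by the uvr8-6 samples could give the same result and was not tested.

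A further comparison, of MIR8175, MIR8176 and MIR5642 as uncertain loci, was written down and then dropped after its result had been seen. What was found is that the MIR8175 mature sequence lies in 22 tRNA-Asp genes and that of MIR8176 in the snoRNA AT4G07075.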
